A study of Mus musculus with 3 samples.

How the data were processed

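Mouse bone marrow-derived dendritic cells were measured on 3 Affymetrix Mouse 430 2.0 arrays, 1 for each of 3 conditions. Per the labels' protocols, total RNA was labelled as biotinylated cRNA and hybridised. The deposited values were probe set signal intensities on a linear scale, made with MAS5 per the submitters' processing notes. The MAS5 version, its target value and its settings are not given in the sources used here. Each column of the deposited table was matched to its condition by its own sample label. No detection calls were used here.

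The table held 45101 probe sets, of which 64 were controls and were left out of every gene result. GEO's platform annotation gave 1 gene for 34945 probe sets and several genes for 932, and did not list 9160, which are unnamed here. Of the probe sets with 1 gene, 99.4% had a gene identifier in the RefSeq gene table, which changed 0 symbols. No genome build is named in the files, so no coordinates are given.

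The rules that follow were fixed before the data were examined. The means of the deposited signals, trimmed by 2% at each end, were 135 on the unstimulated array, 111 on the LPS array and 63.2 on the LPS+8-Br-cAMP array. Because they differed by over 5%, each array was multiplied by a factor that brought it to their average, 0.763, 0.929 and 1.63 in the same order. A single floor was set at the highest of the 3 array medians after scaling, 32.5 (log2 5.02), signals under it were set to it, and log2 was taken. A gene was represented by its probe set with the highest mean signal. It counted as measured in a comparison when it was above the floor on at least 1 of the arrays compared. Differences were log2 differences between arrays, counted as higher or lower at 2-fold. A difference against an array at the floor is a lower bound and is written as at least that size.

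With 1 array per condition there are no replicates, and no test, p-value or standard error was computed. The number of arrays limits the precision. The scatter within these arrays was described by the brightest probe sets of 1 gene. The SD of the difference of their log2 differences, divided by the square root of 2, was 0.45 for LPS against unstimulated over 4029 genes, 0.48 for LPS+8-Br-cAMP against LPS over 3799 genes and 0.56 for LPS+8-Br-cAMP against unstimulated over 3825 genes. This is the error of 1 probe set's log2 difference, called the error of 1 probe set below, not the spread between cultures. Shares of genes are given with 95% Wilson intervals, which cover counting only.

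There were 30 gene lists and 11 marker lists of cell types, dendritic cells among them. The median log2 difference of each list's measured members was placed among 10000 random lists of the same size, matched on mean signal in 20 bins, as a description of these arrays only. A list was set apart when its median lay outside the middle 90% of the random medians. For lists of unrelated genes, 1.5 of the 30 gene lists and 0.55 of the 11 marker lists would be so on each side by chance. Members of a list can move together and some lists share members, so these numbers can be too low here. Genes were named by a rule: for LPS against unstimulated and for LPS+8-Br-cAMP against LPS, the 10 highest and 10 lowest genes past 2-fold whose probe sets all went the same way, up to 4 members of each list with the largest differences, and always Tnf, Il6, Il12b, Il10, Fos and Crem. Of genes at least 2-fold higher with LPS+8-Br-cAMP than on both other arrays, and under 2-fold higher with LPS alone, the 10 with the largest smaller difference were named. Symbols of unnamed transcripts were passed over. Ighm was left out of the lowest genes because its probe sets disagreed.

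The steps were tested on simulated data of the LPS against unstimulated comparison over 11881 genes. Changes were planted only in genes with a mean signal over 2 times the floor, so the shares below do not hold for dimmer genes. The log2 SD was set at 0.34 per array, with no spread between cultures. This is near the error of 1 probe set for LPS+8-Br-cAMP against LPS, 0.48, divided by the square root of 2 to give 1 array. A planted log2 difference of 2 passed 2-fold in 100% of 50 genes, a difference of -2 in 98%, a difference of 1 in 52% and a difference of -1 in 44%. Of unchanged genes 3.24% passed, a share that follows from that SD and is not a false-positive rate for these cultures. A list shift of 0.5 was set apart in 98% of 200 lists of randomly drawn genes and no shift in 5% above and 3.5% below.

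Alternatives were quantile normalization, median scaling, cyclic loess, floors at the 25th and 75th percentiles, a pseudocount in place of the floor, the mean over probe sets, only probe sets ending in _at, thresholds of 1.5-fold and 3-fold, other choices of the LPS-higher genes, unmatched random lists and lists without shared members. Scaling by the hybridisation spikes, the signals as deposited, with no scaling, and a choice of LPS-higher genes without the cAMP-specific class were added after the data were seen. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used, and R 4.3.3 with limma 3.58.1 for cyclic loess.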

Results

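Gene expression was measured in bone marrow-derived dendritic cells (BMDCs), antigen-presenting cells grown from mouse bone marrow for 10 days in the growth factor GM-CSF at 10 ng/ml. The conditions were unstimulated cells, cells given 10 ng/ml lipopolysaccharide (LPS) for 3 h, and cells given LPS together with 100 µM 8-Br-cAMP for 3 h. LPS is a bacterial outer membrane component sensed through Tlr4, and 8-Br-cAMP is a membrane-permeable analogue of the second messenger cyclic AMP. Each condition had 1 array, so no difference below has a replicate check. The array of the LPS+8-Br-cAMP culture was the dimmest, with a deposited median signal of 19.8 against 33.4 with LPS and 42.6 unstimulated. After scaling, 22419, 21932 and 22518 of 45037 probe sets in the same order were above the floor. Control probe sets for Gapdh gave 3' to 5' signal ratios of 0.771 unstimulated, 0.785 with LPS and 0.856 with LPS+8-Br-cAMP, and those for Actb 1.51, 1.36 and 1.14.

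The comparison of LPS with unstimulated cells is between single cultures, both without 8-Br-cAMP. A response to LPS cannot be told apart from another difference between them. No incubation time to match the 3 h with LPS is recorded for the unstimulated cells. Antiviral and inflammatory genes were far higher with LPS. Rsad2, an antiviral enzyme, had a scaled signal of 11245 with LPS and lay at the floor without it, at least 346-fold higher. Cxcl10, a chemokine for activated T cells, was at least 254-fold higher, and the cytokines Il6 and Tnf were higher by at least 7.53 and 7.32 log2 units. Ccl4 and Ccl3, chemokines above the floor on both arrays, were higher by 6.93 and 6.65. Ifit1, Ifit2, Cmpk2 and Cxcl1 completed the 10 highest genes, with log2 differences of at least 7.73, 7.69, 7.14 and 6.52.

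All 32 measured interferon-stimulated genes were at least 2-fold higher with LPS, with a median log2 difference of 3.86. Ifit3 was higher by 6.29, Isg20 by 3.94 and Ifnb1, which encodes interferon beta, by 2.75. Of 19 measured chemokines 15 were at least 2-fold higher (median 3.54), and Ccl12 was higher by at least 3.54. Of 14 proinflammatory cytokines 11 were at least 2-fold higher (median 2.74), among them Il1a by at least 6.45 and Tnfsf9 by 4.06. In the NF-kB pathway and its feedback 20 of 23 genes were at least 2-fold higher (median 1.99). These held the signalling inhibitors Socs3 (4.64), Socs1 (at least 4.35) and Tnfaip3 (3.74), and Nfkbiz (4.05), a nuclear cofactor of NF-kB. The medians of these 4 lists lay at percentile 100 of the random lists.

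The lists of dendritic cell maturation, T cell polarisation and MHC class I presentation lay above the random range with LPS, and MHC class II presentation lay within it. Of 21 maturation genes 13 were at least 2-fold higher (median 1.61, percentile 100), including the costimulatory receptor Cd40 by 5.27 and Il15ra by at least 3.93. T cell polarisation signals had 10 of 19 genes at least 2-fold higher and 1 lower (median 1.17, percentile 100). Among them were Inhba (3.80), the retinoic acid enzyme Aldh1a2 (3.38) and both interleukin subunits Il12a (at least 3.38) and Il12b (3.15). MHC class I presentation had 4 of 14 genes at least 2-fold higher (median 0.89), led by its regulator Nlrc5 (2.99) and the peptide transporter Tap1 (2.67, but 0.34 by its second probe set). MHC class II presentation had a median of 0.077 and 1 of 13 genes past 2-fold, the ubiquitin ligase Marchf1 (1.06), while H2-DMa differed by -0.81. The sign of the class II median turned under other scalings, from -0.21 to 0.31.

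Further lists had medians above the middle 90% of random lists. Other Toll-like receptors and sensors had 9 of 19 genes at least 2-fold higher (median 0.61), such as Casp4 (3.22), Clec4e (3.03), Nod1 (2.41) and Tlr1 (2.38). TLR4 signalling had 6 of 23 (median 0.55), with Ikbke and the adaptor Myd88 both higher by 1.98. Oxidative stress genes had 6 of 16 (median 0.80), with the cystine transporter Slc7a11 (3.79) and the superoxide dismutase Sod2 (3.30). Apoptosis and survival genes had 3 of 15 (median 0.50), with Cflar, an inhibitor of caspase activation, at 2.72. CREB targets, genes switched on by the cAMP-responsive factor CREB, had 7 of 23 higher and 3 lower (median 0.36). Ptgs2, the inducible prostaglandin synthase, was higher by 5.66 and Rgs2 differed by -3.28. Extracellular proteases and coagulation genes had 7 of 21 higher (median 0.29, but -0.049 under cyclic loess), including the plasminogen activator inhibitor Serpinb2 (4.62). Cholesterol synthesis genes had a median of 0.19 with 1 of 17 higher, Idi1 (1.68), and 2 lower, among them Dhcr7 (at least 4.51-fold lower), and the median was -0.093 under spike scaling.

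The lowest genes with LPS were Lpar6, a lysophosphatidic acid receptor, which differed by -4.33, and Cxcr4, the receptor of Cxcl12, which differed by -4.14. Cd300lb (-3.98), Sesn1 (-3.48), Cerk (-3.43), Inpp5d (-3.21), Arrdc3 (-3.13) and Rgs2 (-3.28) followed, with Coro1c and Stk10 at least 11.2-fold and 8.48-fold lower. Chemokine and chemoattractant receptors went both ways. Of 14 measured, 5 were at least 2-fold lower, among them Ccr2 (-2.88) and Cx3cr1 (-2.29), and 3 were higher, among them Ccrl2 (3.65). Circadian clock genes had a median of -0.68 (percentile 1.51), with Per1 at least 5.45-fold lower and Dbp at -1.91. Phagocytosis, scavenging and complement genes had a median of -0.32 (percentile 0.795, but 23.9 against unmatched random lists), although the complement factor Cfb was higher by 3.74.

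In all, 815 of 12283 measured genes were at least 2-fold higher and 1597 at least 2-fold lower, so 33.8% of those past 2-fold were higher. This split depended on the scaling: median scaling gave 1089 higher and 937 lower (53.8% higher) and spike scaling, chosen after seeing the data, 561 and 2585 (17.8%). The signals as deposited, also chosen after seeing the data, gave 555 and 2618 (17.5%). Quantile normalization gave 43.6% and cyclic loess 45.7%. The median of all measured genes was -0.21 in the main scaling, 0.00067 under median scaling and -0.47 under spike scaling, and the 14 gene lists above the random range lay 0.40 to 4.07 above it. The second probe set went the same way for 393 of 426 higher genes, 261 of them past 2-fold, and for 640 of 744 lower genes, 285 past 2-fold.

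**Figure D1:**
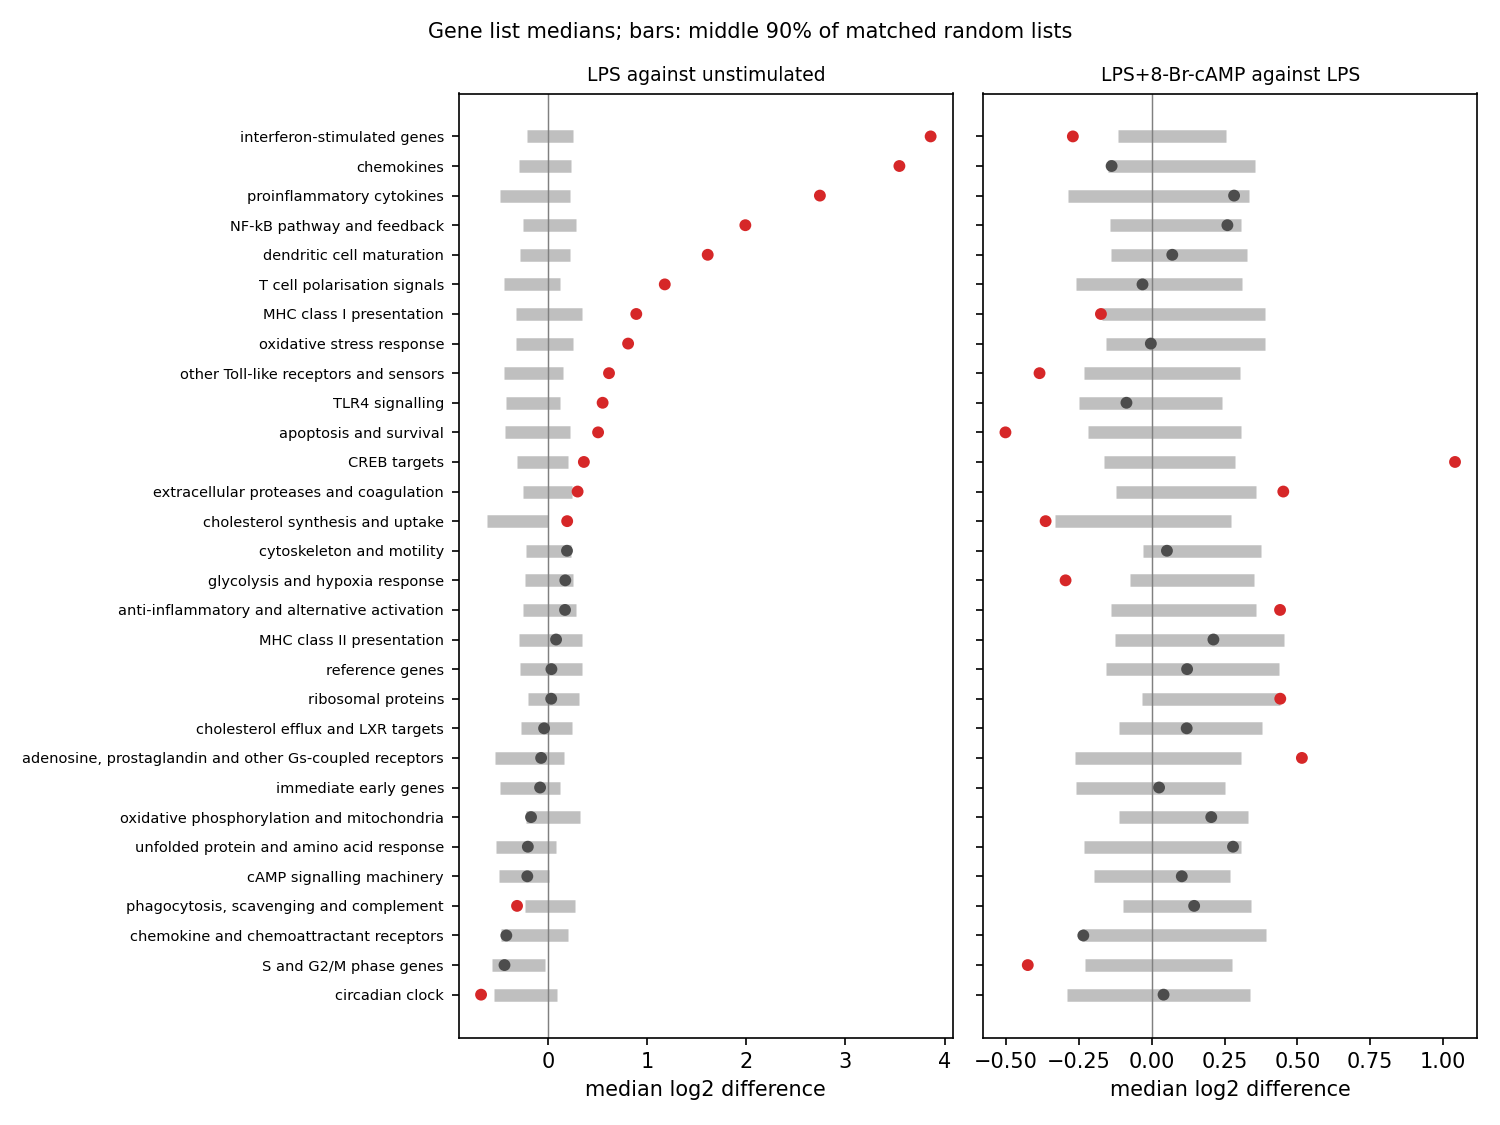
Median log2 difference of each gene list (points) for LPS against unstimulated (left) and LPS+8-Br-cAMP against LPS (right), with grey bars for the middle 90% of matched random lists and red points for medians outside them. Interferon-stimulated genes stood at 3.86 on the left and CREB targets at 1.04 on the right.

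The comparison of LPS+8-Br-cAMP with LPS asks what the analogue adds to LPS. Tnf was 18.4-fold lower with 8-Br-cAMP, at a scaled signal of 283 against 5206. Il12b went the same way but less than 2-fold, at -0.91. Not all inflammatory genes went with Tnf: Il6 differed by 0.59 (-0.22 as deposited, without scaling for the dimmer array). Cxcl1, a neutrophil chemokine, was higher by 1.40 (0.53 by its second probe set). Crem, a cAMP-inducible repressor of CREB targets, was 17.1-fold higher, the phosphatase Dusp1 13.2-fold and the transcription factor Fos 7.41-fold. Il10, an anti-inflammatory cytokine at the floor with LPS, was at least 7.20-fold higher.

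The 8-Br-cAMP culture also differed from both others in transcripts that mark sex and cell type. Xist, transcribed from the inactive X chromosome of females, had a scaled signal of 1716 there and lay under the floor on both other arrays. The Y-linked genes Eif2s3y, Uty, Kdm5d and Zfy2 were above the floor on both other arrays and under it there by their brightest probe sets, 4 of 4. A dimmer Kdm5d probe set read 36.1 there, 34.4 with LPS and 19.1, under the floor, unstimulated. Among the lowest genes against LPS were the antibody transcripts Igkv8-30, at least 37.9-fold lower, Jchain, at least 16.2-fold, and Igha, 15.5-fold. Also among them were Olfm4 (-3.21 to -2.98 across scalings), Pglyrp1 (-3.03 to -2.95), Ddhd1 (-3.21 to -3.01) and Mfsd12 (-3.35 to -2.92). B cell markers had a median of 0.057, within the random range. Ighm, a member of that list whose probe sets disagreed, read 52.5 there against 1495 with LPS by its brightest probe set. Others were lower too, such as 47.2 against 691, 119 against 272 and 40.0 against 198. Among those above the floor on either array, the only exception was a dim probe set at 56.3 against 54.1. Granulocyte markers had a median of -1.07 (percentile 0), all 15 being lower and 8 at least 2-fold, such as Mpo (-2.48), Elane (-2.38), Ltf (-2.16) and Ngp (-1.97). Eosinophil markers had a median of -1.36, with Epx at -1.75 and Prg2 at -1.62. Every difference in this comparison therefore sets apart cultures that differed in these transcripts as well as in 8-Br-cAMP.

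**Figure D2:**
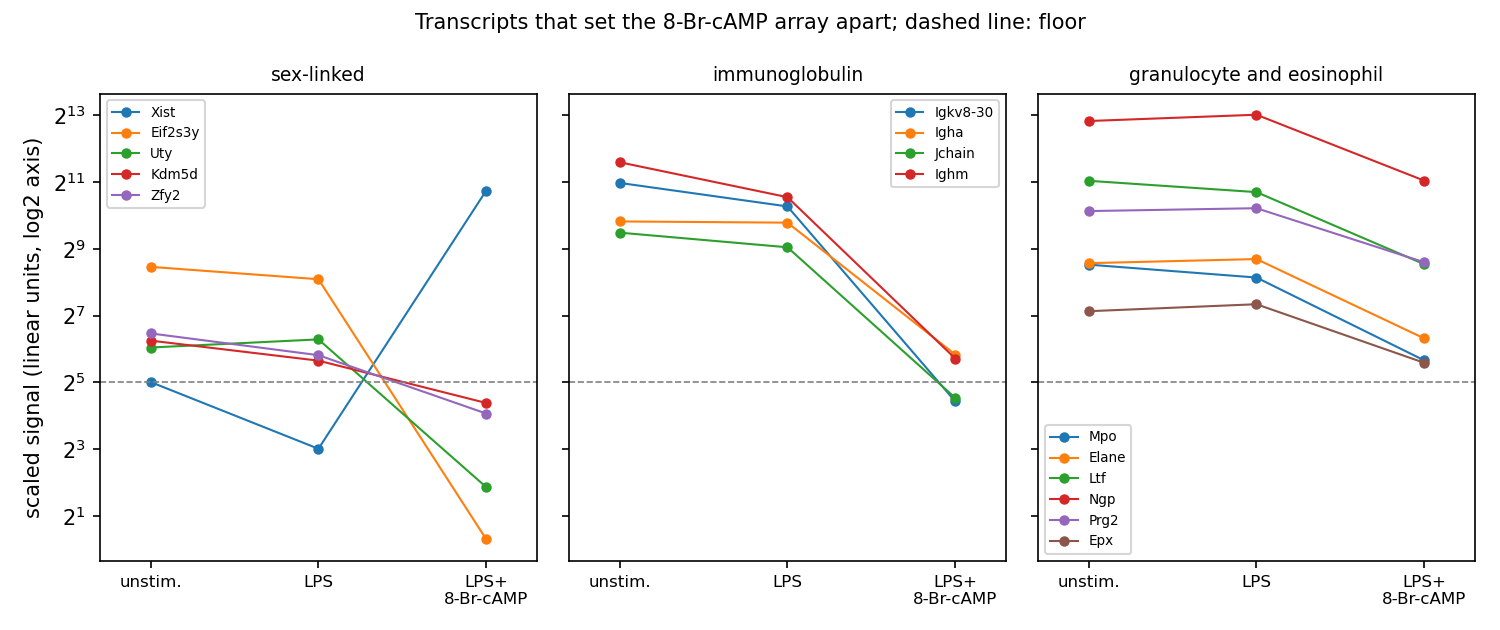
Scaled signal (log2 axis) of sex-linked, immunoglobulin, granulocyte and eosinophil transcripts on the 3 arrays, 1 point per array, joined only to follow a gene, with the floor dashed. Xist stood at 1716 on the LPS+8-Br-cAMP array and under the floor on the others, and Igha at 57.0 there against 881 with LPS.

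CREB targets had the highest median of the 30 gene lists with 8-Br-cAMP, 1.04 (percentile 100), with 13 of 25 genes at least 2-fold higher and 3 lower. The list of adenosine, prostaglandin and other Gs-coupled receptors had 6 of 14 higher and 1 lower (median 0.52, percentile 99.9). Not all its members are such receptors, as it also holds Gpr84 (higher by 1.21) and the receptor accessory proteins of the Ramp family. Among its members Gpr65, an acid-sensing receptor that raises cAMP, was higher by 3.61 and the accessory protein Ramp3 by 2.78. Calcrl differed by -1.66 (-0.38 by its second probe set). Extracellular proteases and coagulation genes had 5 of 21 higher and 2 lower (median 0.45, but 0.10 at the lowest of the other scalings). The protein C receptor Procr was at 2.11, the protease inhibitor Timp1 at 1.91 and tissue factor F3 at -2.16. The percentile of this list was 99.1, but 79.3, within the random range, without members shared with other lists. Anti-inflammatory and alternative activation genes had 7 of 20 higher and 2 lower (median 0.44), with Il4ra at 1.66 and Retnla at 1.72. Immediate early genes split, 8 of 21 higher and 6 lower (median 0.025). Btg2 was higher by 3.12 and Nr4a1 by 2.74, while Egr2 (-1.65) and Atf3 (-1.58) were lower. Ribosomal proteins had a median of 0.44 with 0 of 18 past 2-fold, and 0.085 at the lowest of the other scalings. Their percentile was 95.2, but 91.0 without members shared with other lists.

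Among genes of the LPS response, interferon-stimulated genes had a median of -0.27 with 8-Br-cAMP (percentile 0.25), with 7 of 32 at least 2-fold lower and 0 higher. Ifit3 differed by -1.88, Ifnb1 by -1.64, Isg20 by -1.34 and Ifit2 by -1.30. Chemokines went both ways, 7 of 19 lower and 3 higher. Ccl12 was at least 11.7-fold lower and Ccl3 differed by -2.33, while Cxcl5 was higher by 1.92 and Cxcl14 by 1.90. Other Toll-like receptors and sensors had 5 of 19 lower and 1 higher (median -0.38), with Nod1 at -2.54, Tlr1 at -1.91 and Aim2 at -1.55. Proinflammatory cytokines had 3 of 14 higher and 2 lower (median 0.28), with the granulocyte growth factor Csf3 higher by 3.35 and Osm by 1.85, and Csf2 at least 2.51-fold lower beside Tnf. In dendritic cell maturation 6 of 21 genes were higher and 1 lower (median 0.071), including Cd83 (1.52), Tnfsf4 (1.42) and the lymph node homing receptor Ccr7, 2.83-fold higher. The NF-kB list had a median of 0.26 (percentile 91.3, but 97.2 without members shared with other lists) and MHC class I presentation -0.17 (percentile 4.80, but 11.9 against unmatched random lists), with Tap2 at -1.17 and Nlrc5 at -1.08.

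A further 4 lists had medians below the random range with 8-Br-cAMP, with few members past 2-fold. Of the 30 gene lists 5 lay above that range and 7 below it, where 1.5 on each side would by chance if their genes were unrelated. Apoptosis and survival genes had a median of -0.50 (percentile 0.06) with 3 of 15 at least 2-fold lower. Among them were the death receptor Fas at -1.74 and Cflar at -1.24, but -0.22 by its second probe set. S and G2/M phase genes had a median of -0.43 (percentile 0.23), 21 of 26 being lower, 3 of them at least 2-fold, such as Top2a (-1.36) and Cdc20 (-1.35). Cholesterol synthesis genes had a median of -0.36 (percentile 3.44), 2 of 16 being at least 2-fold lower, Msmo1 at -1.79 and Fdps at -1.06. Glycolysis and hypoxia genes had a median of -0.30 (percentile 0.04), 4 of 24 being at least 2-fold lower. Among them were Egln3 at -1.92 and the glucose transporter Slc2a3 at -1.53, but -0.20 by its second probe set. In that list 11 of 24 genes were higher, and the median was 0.0071 when only probe sets ending in _at were used. Oxidative phosphorylation genes had a median of 0.20, within the random range, with 16 of 23 higher and 0 past 2-fold.

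Of 12572 measured genes 816 were at least 2-fold higher and 730 at least 2-fold lower with 8-Br-cAMP, 52.8% of those past 2-fold being higher. The signals as deposited, with no scaling and chosen after seeing the data, gave 93 and 2882 (3.13% higher), with a median of all measured genes of -0.65 against 0.049 after scaling. The deposited trimmed mean of the 8-Br-cAMP array was 0.571 times that of the LPS array and its hybridisation spikes 0.544 times. The counts from deposited signals therefore carry the dimness of that array. The second probe set went the same way for 264 of 344 higher genes, 100 of them past 2-fold, and for 267 of 346 lower genes, 95 past 2-fold.

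**Figure D3:**
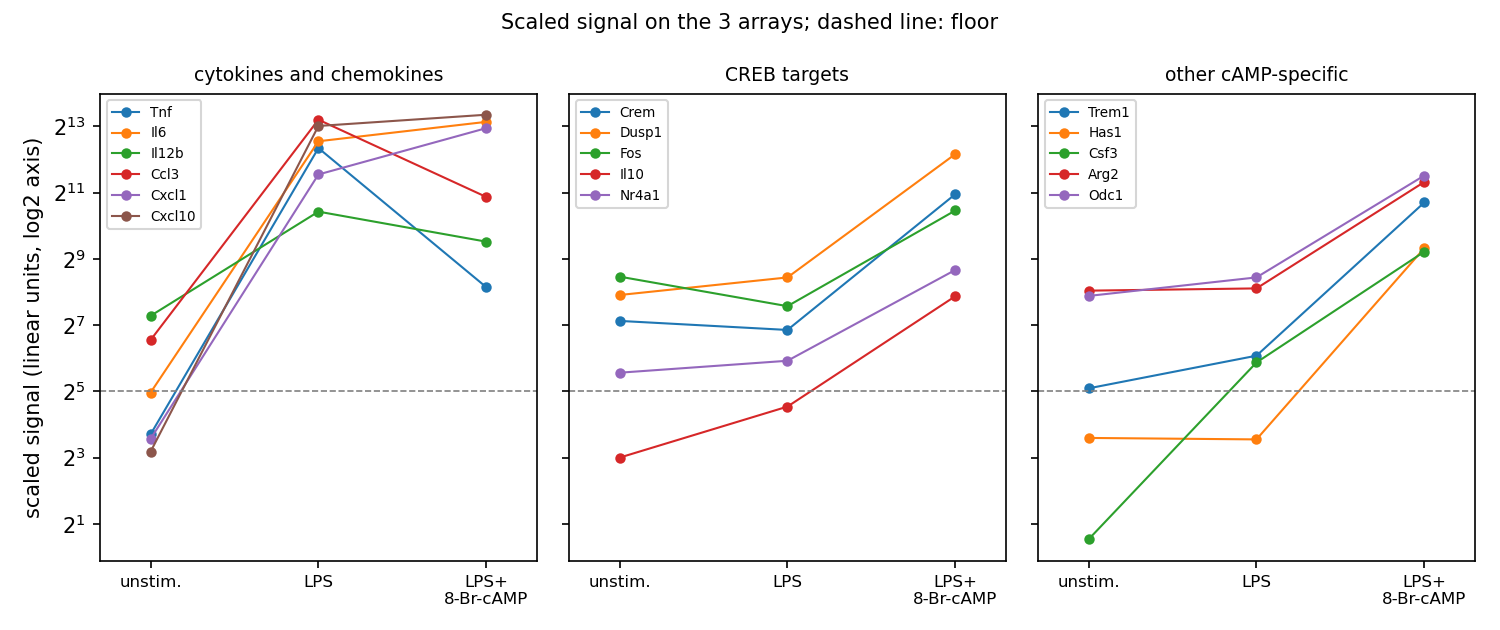
Scaled signal (log2 axis) of named genes on the 3 arrays, 1 point per array, joined only to follow a gene, with the floor dashed. Tnf stood under the floor unstimulated, at 5206 with LPS and at 283 with LPS+8-Br-cAMP, and Crem at 116 with LPS and 1983 with LPS+8-Br-cAMP.

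The series' stated question was which genes were specifically higher with cAMP. No array had 8-Br-cAMP without LPS, so an effect of the analogue alone cannot be told apart from one that needs LPS as well. A class of 360 genes was at least 2-fold higher with LPS+8-Br-cAMP than on both other arrays and under 2-fold higher with LPS alone. Its size depended on the floor and the scaling, with 1109 genes at a floor at the 25th percentile, 165 at the 75th and 36 with the signals as deposited. The deposited signals keep the dimness of the 8-Br-cAMP array, whose hybridisation spikes were 0.544 times those of the LPS array. Of the 360 genes, 41.7% stayed in the class at the higher floor and 53.6% with a pseudocount, while quantile normalization, median scaling and cyclic loess kept 91.1% to 96.9% and spike scaling 66.9%. Of the class, 94 genes were under the floor on both other arrays, where background on the 8-Br-cAMP array counts most. They were 1.59% of the 5910 genes so placed, and 1 of 72 such probe sets of olfactory and vomeronasal receptors, looked at after seeing the data (1.39%, interval 0.25 to 7.46) met the same rule. The class held 9 of the 25 CREB targets above the floor on at least 1 array, 7 immediate early genes and 6 anti-inflammatory genes. After Xist, its leading genes were Trem1, an amplifying receptor of myeloid cells, 24.7-fold above LPS, Has1, a hyaluronan synthase at least 19.7-fold above LPS, and Crem, Dusp1 and Csf3. Arg2, a mitochondrial arginase, was higher by 3.21, Odc1, the first enzyme of polyamine synthesis, by 3.08, Rhou by 3.12 and Sptssb by at least 3.20. Of 150 class members with a second probe set above the floor, 117 were higher by it too (78.0%, interval 70.7 to 83.9), 54 of them at least 2-fold. Ackr3, Mucl1 and Med18, also among the 10 highest genes against LPS, were higher by at least 15.9-fold, by 3.46 log2 units and by at least 3.34. As Xist is in the class, the class may also take up differences between the cultures that are not effects of 8-Br-cAMP.

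Genes higher with LPS were also followed to the 8-Br-cAMP array. Of the 815 genes, 148 were at least 2-fold lower there (18.2%, interval 15.7 to 21.0) and 44 at least 2-fold higher (5.40%, 4.05 to 7.17), while 623 were neither. Counted at any size, 64.8% were lower, against 45.5% of the other measured genes. Chosen by the mean of both LPS-stimulated arrays, 76 of 828 genes were lower (9.18%, 7.40 to 11.3) and 131 higher (15.8%, 13.5 to 18.5), and 44.0% were lower at any size. That choice uses the 8-Br-cAMP array as well, so it took up 87 genes of the cAMP-specific class, all among the 131, and dropped 72 of the 148. Without the class, an alternative chosen after seeing the data, 10.3% (8.27 to 12.6) of 741 genes were lower and 5.94% (4.45 to 7.88) higher. Measured by the second probe set of 439 genes, 12.3% (9.55 to 15.7) were lower and 6.61% (4.64 to 9.33) higher, the direction of the first choice. Among the 11757 other measured genes 4.95% were at least 2-fold lower and 6.57% higher. Both comparisons share the LPS array. Across 13289 genes, which are not independent, their log2 differences had a correlation of -0.19, and 100 simulations with no effect gave -0.50. The covariance was -0.11 in the data and -0.10 in the simulations. Both simulated values follow from the shared array and the error put in, so neither is a test. That error, 0.34 per array, came from the probe sets of 1 gene on these arrays. In the simulations no gene responded to LPS, so the 174 that passed on average as LPS-higher did so by error alone. Of these, 92.3% were lower at any size. In the data 815 passed, and the second probe set was higher too for 393 of 426 with such a probe set. The simulated share therefore does not measure how much of the 64.8% the shared array accounts for. By the second probe set, 60.8% (56.2 to 65.3) of the 439 genes were lower at any size. Both probe sets read the same LPS array, so neither share by itself shows lowering by 8-Br-cAMP. Of the 1597 genes lower with LPS, 187 were at least 2-fold higher with 8-Br-cAMP, among them Rgs2 (1.82), Lpar6 (1.47) and Arrdc3 (1.39), and 48 were lower.

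**Figure D4:**
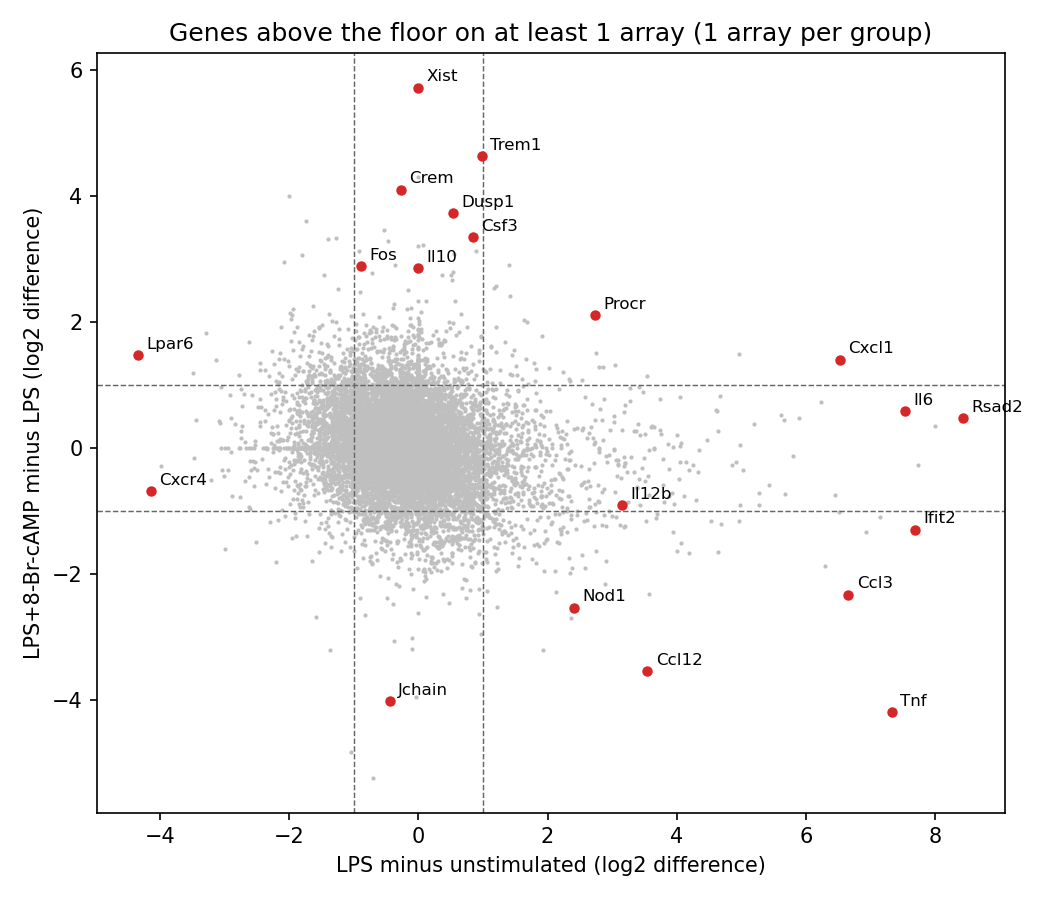
Log2 difference of LPS+8-Br-cAMP against LPS (vertical) and of LPS against unstimulated (horizontal) for each of the 13289 genes above the floor on at least 1 array, with dashed lines at 2-fold and named genes in red. Tnf stands at 7.32 and -4.20, Crem at -0.27 and 4.10.

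LPS+8-Br-cAMP against unstimulated cells sets the joint treatment against none, with the same differences of sex-linked and granulocyte transcripts between the cultures. Tnf was still at least 3.12 higher and Il6 at least 8.11 higher than in unstimulated cells, and Il12b was higher by 2.24. Crem was higher by 3.83 and Fos by 2.00. Nod1 differed by -0.13. Of 12793 measured genes 1198 were at least 2-fold higher and 2018 lower (37.3% higher), against 1672 and 1208 (58.1%) under median scaling, 836 and 2678 (23.8%) under spike scaling and 286 and 6125 (4.46%) as deposited. Interferon-stimulated genes had a median of 3.63, chemokines 3.05 and CREB targets 1.68, each at percentile 100.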

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

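The tests on sex-linked transcripts, on scaling of the granulocyte markers, on a culture from another animal and on background, and the choice of LPS-higher genes without the cAMP-specific class, were chosen after the result was seen. The tests on the shared LPS array, on single probe sets, on fewer granulocytes and on scaling of the genes higher with 8-Br-cAMP were set before it, but the spike scaling used in the last of these was added after the data were seen, and reading the second probe sets by their intervals was decided after their shares were seen.

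Probe sets outside the gene results also differed with LPS. Of the probe sets that the annotation does not list, 236 were at least 2-fold higher and 231 lower with LPS than unstimulated, and of those listed for several genes, 46 and 49.

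Sex-linked and granulocyte transcripts set the 8-Br-cAMP array apart. Scaling is argued against, since the Xist difference was 5.51 at its smallest under the 4 other scalings and the granulocyte median minus that of all genes was -1.25 under cyclic loess and -1.26 under quantile normalization, which can shift bright and dim genes apart. Bone marrow from an animal of the other sex is a candidate explanation for the sex-linked part, as 4 of 4 Y-linked genes above the floor elsewhere lay under it there. A dimmer Kdm5d probe set read 36.1 there, just over the floor of 32.5, but also lay under the floor unstimulated, at 19.1. For the granulocyte part, fewer such cells in that culture stay open, as the SD of the markers' differences was 1.72 times the error of 1 probe set. For the granulocyte median of -1.07 a culture from another animal cannot be told apart from an effect of 8-Br-cAMP either, because no condition has a second culture.

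Genes were higher on the 8-Br-cAMP array than on both others. Of the class of 360 genes, 91.1% was kept under quantile normalization, 96.9% under median scaling and 91.7% under cyclic loess, all past the 80% set against scaling. Spike scaling kept 66.9%, between that and the 50% set for it, so scaling stays open for part of the class. The signals as deposited, outside this test and with the dimness of that array left in, kept 9.17%. The second probe set was higher in 78.0% of 150 genes, at least 2-fold in 54, so error of single probe sets may account for some members. The interval of 70.7 to 83.9, which covers counting only, lies above 50%. Both probe sets read the same array, so their agreement does not bear on error shared across an array or on the culture. Background on that array stays open for the 94 members under the floor on both other arrays, which were 1.59% of such genes, as 1 of 72 such receptor probe sets also met the rule, too few to decide. The CREB target list had 13.3 times the share of all measured genes in the class, which is consistent with an effect of the analogue but does not exclude the other culture.

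More LPS-higher genes lay at least 2-fold below their LPS level on the 8-Br-cAMP array than above it, and 64.8% lay below it at any size. The LPS array shared by both comparisons stays open as an explanation. In simulations with no effect, 92.3% of the genes that passed as LPS-higher lay below their LPS level at any size. Those genes passed by error alone, so this share does not measure what the shared array does in the data. With genes chosen by the mean of both LPS-stimulated arrays 9.18% were at least 2-fold lower and 15.8% higher, which met the bound set for it, and 44.0% were lower at any size against 45.5% of other genes. But 87 of the 131 higher genes entered by their level on the 8-Br-cAMP array, so that bound was wrong. Without the cAMP-specific class 10.3% were lower and 5.94% higher, but leaving out genes high on the 8-Br-cAMP array favours lower ones in turn. Measured by the second probe set, which keeps the choice by the LPS array, 12.3% were lower and 6.61% higher, and 60.8% were lower at any size. Error of single probe sets alone would put the second probe set lower in about 50% of the genes at least 2-fold lower. It was lower in 49 of 59 (83.1%), at least 2-fold in 20. The interval of 71.5 to 90.5, which covers counting only, lies above 50% but includes values under the 80% set beforehand. Here too both probe sets read the same array. A general dampening of the LPS response by 8-Br-cAMP is therefore neither shown nor excluded here.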

How the results depend on the processing

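Spike scaling, the signals as deposited and the choice of LPS-higher genes without the cAMP-specific class were chosen after the data were seen, and all other alternatives were planned. Quantile normalization and cyclic loess kept each count and class within 1.5 times its main value. Of the values of named genes under the alternatives, 2850 lay within the error of 1 probe set of the main value, 465 lay beyond it and 2 changed sign in a gene past 2-fold in the main setting. With genes under 2-fold included, the sign turned under at least 1 alternative for 27 of 336 named values, and for 8 of these under another scaling. Of the list medians 751 lay within that error, 50 beyond it and 12 changed sign in a list set apart. List percentiles kept their side of the random range in 153 cases and changed it in 11. Against random lists not matched on signal, MHC class I with 8-Br-cAMP (percentile 11.9) and phagocytosis with LPS (23.9) were no longer set apart, while anti-inflammatory genes (97.7), glycolysis (98.5) and cytoskeleton (99.0) with LPS were. Without members shared between lists, extracellular proteases (79.3) and ribosomal proteins (91.0) with 8-Br-cAMP and dendritic cell markers with LPS (77.5) were no longer set apart, while proinflammatory cytokines (96.3), chemokines (4.06) and the NF-kB pathway (97.2) with 8-Br-cAMP were. The cause was not tested for any value below unless stated. Low signal over background limits dim genes, as the effect of the floor shows.

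Under median scaling the genes at least 2-fold lower were 937 with LPS and 1208 with LPS+8-Br-cAMP against unstimulated, and the class lower with LPS and again with 8-Br-cAMP had 28 genes. Cyclic loess put the medians with LPS at -0.049 for extracellular proteases and -0.084 for dendritic cell markers. Spike scaling gave 2585 genes lower with LPS, 93 LPS-higher genes lower with 8-Br-cAMP, and medians with LPS of -0.093 for cholesterol synthesis and -0.076 for dendritic cell markers.

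A floor at the 25th percentile counts more dim genes by construction. It gave 1839 higher and 2640 lower genes with LPS, 2326 and 1873 with 8-Br-cAMP against LPS, and 2691 and 3099 against unstimulated. The cAMP-specific class had 1109 genes. LPS-higher genes were lower in 531 and higher in 91 cases with 8-Br-cAMP, and LPS-lower genes higher in 728 and lower in 154. The share of LPS-higher genes at least 2-fold lower was 28.9%. Medians were 3.997 for chemokines and 0.11 for plasmacytoid dendritic cell markers with LPS, and 1.61 for erythroid markers with 8-Br-cAMP.

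A floor at the 75th percentile removes dim genes. It gave 596 lower genes with LPS, 302 higher and 304 lower with 8-Br-cAMP against LPS, and 721 and 839 against unstimulated. The cAMP-specific class had 165 genes. LPS-higher genes were lower in 91 and higher in 27 cases with 8-Br-cAMP, LPS-lower genes higher in 42 and lower in 10, and the share lower was 15.6%. Medians with LPS were 2.88 for chemokines, -0.62 for Gs-coupled receptors and 0.53 for plasmacytoid dendritic cell markers, and with 8-Br-cAMP -0.46 for B cell markers.

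The pseudocount gave 1026 lower genes with LPS, 94 LPS-lower genes higher and 27 lower with 8-Br-cAMP, and 15.4% of LPS-higher genes lower. Its medians with LPS were 0.58 for T cell polarisation, 0.033 for plasmacytoid dendritic cell markers and -0.31 for erythroid markers, and -0.60 for eosinophil markers with 8-Br-cAMP. The mean over probe sets gave 20 LPS-lower genes lower again and -0.32 for B cell markers with LPS. With only probe sets ending in _at, medians with LPS were 2.14 for proinflammatory cytokines, -0.51 for LXR targets and -0.30 for B cell markers. With 8-Br-cAMP they were 0.53 for immediate early genes, 0.0071 for glycolysis and -0.43 for mast cell markers. The same setting put Fabp4 with LPS at -0.51 and Irak1 with 8-Br-cAMP at 0.28, against 1.02 and -1.21 in the main setting, since it takes another probe set of each.

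At 1.5-fold there were 1710 higher and 3516 lower genes with LPS, 2271 and 1988 with 8-Br-cAMP against LPS, and 2361 and 3774 against unstimulated. The classes held 1026 cAMP-specific genes, 613 LPS-higher genes lower and 188 higher, and 790 LPS-lower genes higher and 391 lower. At 3-fold there were 406 and 425 with LPS, 182 and 154 with 8-Br-cAMP against LPS, and 506 and 688 against unstimulated. The classes then held 90 cAMP-specific genes, 24 LPS-higher genes lower and 4 higher, and 21 LPS-lower genes higher and 3 lower. These follow from the thresholds themselves.

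Choosing LPS-higher genes by the mean of both LPS-stimulated arrays gave 9.18% at least 2-fold lower and 15.8% higher, which turned the direction. That choice took up 87 genes of the cAMP-specific class, higher by definition, and dropped 72 of the lower genes. Without the class 10.3% were lower and 5.94% higher. Measured by the second probe set, 12.3% were lower and 6.61% higher.

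With the signals as deposited, the 8-Br-cAMP array's lower brightness moved the median of all measured genes to -0.65 against LPS and -1.08 against unstimulated, which by construction lowers every list. There were 2618 lower genes with LPS, 93 higher and 2882 lower with 8-Br-cAMP against LPS, and 286 and 6125 against unstimulated. The classes held 36 cAMP-specific genes, 311 LPS-higher genes lower and 5 higher, and 32 LPS-lower genes higher and 416 lower. The shares of LPS-higher genes were 56.0% lower and 0.901% higher. Medians with LPS were -0.095 for cholesterol synthesis, -0.50 for LXR targets and -0.078 for dendritic cell markers.

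With signals as deposited, list medians set apart in the main setting changed sign for 5 lists with 8-Br-cAMP against LPS. These were -0.37 for anti-inflammatory genes, -0.12 for Gs-coupled receptors, -0.58 for extracellular proteases, -0.37 for ribosomal proteins and -0.13 for natural killer cell markers. Among LPS response lists the medians were -0.53 for proinflammatory cytokines, -0.95 for chemokines, -1.08 for interferon-stimulated genes, -0.55 for the NF-kB pathway and -0.85 for TLR4 signalling. Other sensors had -1.19, dendritic cell maturation -0.74, MHC class II -0.60, MHC class I -0.98 and T cell polarisation -0.59. CREB targets had 0.25, immediate early genes -0.75, cAMP machinery -0.67, phagocytosis -0.65 and the circadian clock -0.54. Metabolic lists had -1.10 for glycolysis, -0.61 for oxidative phosphorylation, -1.05 for cholesterol synthesis and -0.65 for LXR targets. Stress and growth lists had -0.49 for the unfolded protein response, -0.81 for oxidative stress, -1.23 for S and G2/M phase genes and -1.32 for apoptosis. Cytoskeleton genes had -0.77 and reference genes -0.69. Marker lists had -1.88 for granulocytes, -0.73 for macrophages, -0.65 for dendritic cells, -0.76 for plasmacytoid dendritic cells, -0.46 for mast cells, -0.68 for B cells and -0.99 for stromal cells.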

Other observations

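The olfactory and vomeronasal receptor probe sets were chosen after the data were seen, while the list medians and spike levels were planned.

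Genes of the oxidative stress list parted with 8-Br-cAMP. Hmox1, the heme-degrading oxygenase, differed by -2.46, while the metallothioneins Mt2 and Mt1 were higher by 1.51 and 1.40, and Mt2 had already been higher by 2.74 with LPS. The median of that list was -0.0030. Cytoskeleton and motility genes had 4 of 26 at least 2-fold lower and 0 higher, with Rhob at -2.28 and the integrin chain Itgb3 at -2.22, at a median of 0.052. The complement receptor C3ar1 differed by -2.63, and the list of chemokine and chemoattractant receptors had a median of -0.23. Of the lipid transport genes Abca1 (1.71) and Apoc2 (1.76) were higher and Fabp4 (-1.65) lower, and the list of cholesterol efflux and LXR targets had a median of 0.12. Klrb1b was higher by 1.92, and natural killer cell markers had a median of 0.59 (percentile 95.7). In the circadian clock Bhlhe40 was higher by 1.56 and Nr1d2 differed by -1.91, at a median of 0.041. Fcgr4, an activating antibody receptor, was higher by 1.76 and the efferocytosis receptor Mertk differed by -1.65, at a list median of 0.15.

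The other lists lay within the middle 90% of random lists with 8-Br-cAMP. Their medians were 0.21 for MHC class II presentation, -0.087 for TLR4 signalling, 0.10 for cAMP signalling machinery, 0.20 for oxidative phosphorylation, 0.28 for the unfolded protein response, -0.032 for T cell polarisation signals and 0.12 for reference genes. Among marker lists they were 0.079 for macrophages and monocytes, 0.21 for dendritic cells, -0.043 for plasmacytoid dendritic cells, 0.15 for mast cells and basophils, 0.0035 for T cells, 0.057 for B cells, 0.23 for erythroid cells and -0.18 for stromal cells. Across the 4 other scalings the sign turned for MHC class II, LXR targets, oxidative stress, cytoskeleton, T cell polarisation, reference genes, macrophages, dendritic cells, plasmacytoid dendritic cells and T cells.

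With LPS, B cell markers had a median of -0.81 (percentile 1.17) and dendritic cell markers 0.21 (percentile 95.4, but 77.5 without members shared with other lists). Lists within the random range had medians of -0.085 for immediate early genes, 0.17 for anti-inflammatory genes, 0.17 for glycolysis, 0.19 for cytoskeleton, -0.21 for cAMP signalling machinery, -0.074 for Gs-coupled receptors, -0.43 for chemokine receptors, -0.18 for oxidative phosphorylation, -0.044 for LXR targets, -0.21 for the unfolded protein response, -0.44 for S and G2/M phase genes, 0.028 for ribosomal proteins and 0.030 for reference genes. Other marker lists had -0.0057 for granulocytes, -0.024 for macrophages and monocytes, -0.42 for plasmacytoid dendritic cells, -0.071 for mast cells and basophils, 0.11 for eosinophils, -0.22 for T cells, -0.32 for natural killer cells, 0.30 for erythroid cells and -0.19 for stromal cells. Across the same scalings the sign turned for all of these except chemokine receptors, S and G2/M phase genes, B cells, plasmacytoid dendritic cells, natural killer cells and erythroid cells.

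The 80 probe sets of olfactory and vomeronasal receptors had a 95th percentile of scaled signal of 59.7 on the 8-Br-cAMP array, 35.6 on the LPS array and 32.7 on the unstimulated array, so dim signals there stood higher above the floor of 32.5. Deposited hybridisation spikes on it were 0.544 times those of the LPS array, and the spikes added to the RNA 0.686 times.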
